A study of Sus scrofa with 57 samples.

How the data were processed

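RNA was sequenced from 57 single parthenogenetic pig blastocysts, 37 injected with Cas9 and 20 with tdTomato. Per the labels, RNA was purified on RNeasy MinElute columns and libraries were built with a TruSeq RNA kit. Groups were taken from the sample titles. The leading digit of each embryo code in the descriptions was used as a code set, because 18 of the 20 tdTomato libraries fall in code set 2 and 21 of the 37 Cas9 libraries in code set 3.

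The authors deposited a gene table per library with estimated counts of reads, TPM, length and effective length, in the layout of Salmon. The submitters' processing notes name Salmon 0.8.2, DESeq with no version and DESeq2 1.20.0, without their roles. The reference transcriptome and genome build are not given in the sources used here. The authors also deposited a table of the whole series named as raw counts. Its values are TPM: its columns sum to about 1e6, and the largest difference from the TPM of the same library's own table was 0. The tests had been planned on that table before the data were examined. Because it holds TPM, they were run on the estimated counts in the deposited library tables, rounded to whole numbers. All 57 columns of the series table were matched to a library. The tables hold 26653 gene rows, of which 26624 match symbols of the RefSeq annotation of the pig assembly Sscrofa11.1, used here for gene names and gene types only. A row named SPCas9 was added by the authors. No row for tdTomato was used here.

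Library totals were 3.95 to 32.8 M estimated reads (M, 1e6). A count of 0 in a library allows up to 3 reads, or 3 divided by the library total in M for RPM, and such limits cover counting error only. Genes were kept by edgeR's filterByExpr on the treatment groups (12086 genes; 11882 in code set 2), scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersions, with the code set as an additive term. p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors are the fitted log2 change divided by the square root of F. CPM are counts per 1e6 TMM-scaled reads, given as mean ± SD. Fits of code set 2 alone, of all libraries without the code set term, and of code sets within Cas9 blastocysts used the same steps.

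The 23 gene lists were fixed in advance, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members, 21 of 23, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The list of mitochondrially encoded mRNAs matched 0 of 26 names and was not tested, and only 3 of 14 blood and somatic markers had enough reads, too few for a list test. Named genes are (a) the 12 largest rises and 12 largest falls among genes with a symbol, adjusted p under 0.05, a mean of at least 5 CPM and the same sign in code set 2, (b) the 3 members of each list with the smallest p, and (c) 14 genes fixed in advance, of which BAX, SOX2 and SOX17 were among those with too few reads. Some genes taken by the rule, and 1 list, are not reported here. Library medians were compared by two-sided permutation tests with 100000 resamples.

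On counts simulated from the real means, dispersions and library totals of the comparison of Cas9 and tdTomato blastocysts (12086 genes), the gene test recovered 69% of 100 genes changed 2-fold and 97% of 100 genes changed 3-fold, with 5 false calls among 171. A simulated rise of 1 list was called, with 0 of 20 other lists. Genes were drawn independently there, with no code set differences. False calls of genes or lists from variation that genes share in the real libraries are therefore not covered. The smallest chi-square per degree of freedom between libraries of a group was 11.1, far above sampling noise, so no library was counted as a duplicate.

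Alternatives to the gene test were no code set term, code set 2 alone, the replicate number of the titles as a block, leaving out the 2 lone tdTomato libraries, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no count filter, a stricter filter (at least 1 CPM in 20 libraries), limma-trend on log2(TPM + 1), the number of detected genes as a covariate, and each tdTomato library left out in turn. Added after seeing the data were scaling by library totals, upper-quartile factors, thinning all libraries to 3.95 M reads, the KATNAL1 and MLST8 share as a covariate, effective length offsets, bias-adjusted dispersions, and leaving out 5 genes with over 1% of reads. The score built from code set 2 was also chosen after seeing the data. The installed edgeR's default dispersions were adopted for the main test after the bias-adjusted ones, which call 3895 genes in place of 3632, had been run.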

Results

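Single pig blastocysts were profiled by RNA sequencing after injection of Cas9, the nuclease used for genome editing, or of tdTomato, a red fluorescent protein. The embryos were parthenotes, grown from matured oocytes that had been activated with an electric pulse and not fertilized. Per the title of the series, Cas9 was given without a guide RNA, and the comparison asks how the transcriptomes of such embryos differ from those given tdTomato. The form and dose of what was injected are not given in the sources used here. There were 37 Cas9 and 20 tdTomato libraries, each from 1 blastocyst. The embryo codes begin with a digit from 1 to 3, called the code set here, whose meaning is not given in the sources used here. Code set 1 held 7 Cas9 and 1 tdTomato library, code set 2 held 9 and 18, and code set 3 held 21 and 1. Nothing states how many oocyte pools or injection days the embryos came from, so p-values measure the spread between these blastocysts. Cas9 libraries had a median of 12.1 M estimated reads (M, 1e6; 5.20 to 32.8) and 16627 genes with at least 1 read. tdTomato libraries had a median of 8.01 M (3.95 to 16.2) and 15766 genes. Both differences passed a two-sided permutation test within code sets (p = 0.00017 for reads, p = 0.00039 for genes, adjusted p = 0.000237 and 0.00039 over 5 library measures), and both had the same sign in code set 2 alone (p = 0.0001 and 0.00012).

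The libraries had an unusual makeup that also differed between the groups. KATNAL1, a subunit of a microtubule-severing enzyme, and MLST8, a subunit of the mTOR complexes, together took a median of 10.2% of reads in Cas9 blastocysts (6.50% to 14.7%) and 5.21% in tdTomato blastocysts (3.29% to 8.45%; two-sided permutation test within code sets, p = 0.00011). The estimated reads of these genes were nearly equal in all 57 libraries, with a KATNAL1 to MLST8 ratio between 0.866 and 1.14, although the genes are unrelated. Whether reads are shared between these genes was not tested, for want of the reference sequences, so the values of both are uncertain.

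Reads of the Cas9 sequence, which the authors' tables list as an added gene named SPCas9, were present in every Cas9 blastocyst, with 5 to 7061 estimated reads and a median of 42. In tdTomato blastocysts there were 0 to 33 reads with a median of 2.5. In reads per 1e6 library reads (RPM), the medians were 3.62 in Cas9 (0.537 to 642) and 0.296 in tdTomato libraries (0 to 8.35), a difference that passed a two-sided permutation test within code sets (p = 0.00019). The same test in code set 2 alone gave medians of 3.46 and 0.284 (permutation p = 0.00173). The ranges overlapped. The tdTomato library with replicate number 6 had 8.35 RPM, more than 32 of the 37 Cas9 libraries. The 4 tdTomato libraries with 0 reads can hold up to 3 reads by counting error alone. The edgeR log2 fold change was 3.13 ± 1.07 (SE; adjusted p = 0.0202), and 2.54 ± 0.68 in code set 2 (adjusted p = 0.00457). Over 14 alternatives its log2 fold change ran from 0.91 to 5.55 and its adjusted p from 3.41e-06 to 0.297, and 6 of them ended the call. These were leaving out the lone tdTomato libraries of code sets 1 and 3 (2.56, adjusted p = 0.0674), thinning (2.89, 0.0532), limma-voom (2.75, 0.0988), limma-trend (0.91, 0.110), and the number of detected genes (3.74, 0.104) or the KATNAL1 and MLST8 share (3.60, 0.297) as a covariate.

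**Figure D1:**
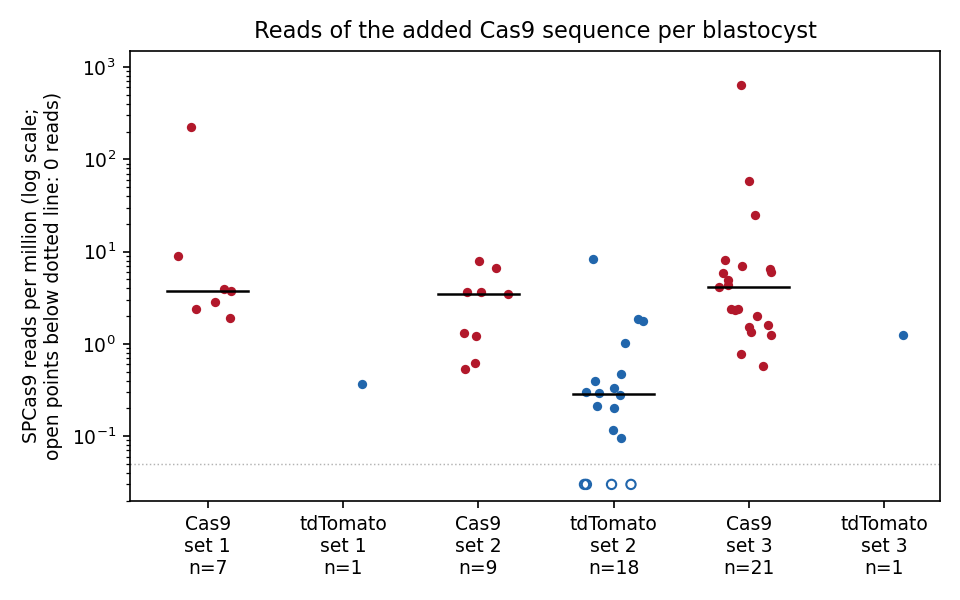
SPCas9 RPM in each blastocyst, by group and code set, on a log axis; filled points are libraries, open points under the dotted line are libraries with 0 reads, and black lines are medians. Cas9 libraries lie between 0.537 and 642 RPM and tdTomato libraries between 0 and 8.35, so the ranges overlap.

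Cas9 and tdTomato blastocysts differed in the abundance of many transcripts. Of the genes taken by the fixed rule for named genes, the largest rise in Cas9 blastocysts was that of TLDC2, which had reads in all 37 Cas9 libraries and 0 reads in 17 of 20 tdTomato libraries, which held 44 reads in all (log2 fold change 5.25 ± 0.52, SE; adjusted p = 1.02e-12; 9.28 ± 6.05 CPM in Cas9 (SD, n = 37) and 0.260 ± 0.686 CPM in tdTomato blastocysts (SD, n = 20)). CYP26A1, which breaks down retinoic acid, rose by 3.41 ± 0.80 on the log2 scale (adjusted p = 0.000516; adjusted p = 0.113 in limma-voom), although its Cas9 libraries ranged from 0 to 127 CPM. Its Cas9 means were 0.230, 6.98 and 12.2 CPM in code sets 1, 2 and 3, against 0.518 CPM in tdTomato blastocysts, and with the KATNAL1 and MLST8 share as a covariate it was at 0.56 (adjusted p = 0.904). OTOF, a calcium sensor of synaptic vesicle release, rose by 2.73 ± 0.30, and TUBA4A, an alpha-tubulin, by 2.60 ± 0.37. The transcription factors TFAP4 and IKZF3 rose by 2.36 ± 0.22 and 2.17 ± 0.19. TFAP4 stood at 5.89 to 22.5 CPM in Cas9 libraries and at 0.465 to 4.16 CPM in tdTomato libraries, with no overlap. The other rises taken by the fixed rule were those of FADS6 (2.32 ± 0.21), the gonadotropin-releasing hormone receptor GNRHR (2.30 ± 0.21), the proton channel OTOP2 (2.28 ± 0.23), the steroid-metabolizing enzyme AKR1C1 (2.21 ± 0.22) and the peroxisomal transporter ABCD2 (2.16 ± 0.20). Each of these genes also passed in code set 2 alone.

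Transcripts that fell in Cas9 blastocysts included products of the oocyte. BMP15, an oocyte growth factor, fell by 2.76 ± 0.48 on the log2 scale (adjusted p = 3.57e-06; 2.05 ± 1.84 CPM in Cas9 (SD, n = 37) and 17.5 ± 24.9 CPM in tdTomato blastocysts (SD, n = 20)). BTG4, an adaptor in the removal of poly(A) tails from maternal mRNA, had a log2 fold change of -2.61 ± 0.54 (adjusted p = 9.68e-05). MCUB, an inhibitory subunit of the mitochondrial calcium channel, had one of -2.79 ± 0.48, which did not pass in code set 2 (adjusted p = 0.0601). Further falls taken by the rule were CCSER1 (-2.21 ± 0.42), PEX5L (-2.15 ± 0.59), the microfibril protein MFAP5 (-2.03 ± 0.42), AFAP1L2 (-1.88 ± 0.42), the nuclear receptor RORB (-1.87 ± 0.46), the GABA receptor subunit GABRR1 (-1.86 ± 0.57), FAM46C (-1.74 ± 0.39) and ECI1, an enzyme of fatty acid oxidation (-1.63 ± 0.30). Of these, GABRR1 did not pass in code set 2 (adjusted p = 0.0533). In limma-voom the calls of MCUB, BTG4, RORB and GABRR1 were lost (adjusted p = 0.0646, 0.0979, 0.125 and 0.0923). With the KATNAL1 and MLST8 share as a covariate all of these falls except MCUB and BTG4 lost their call. BMP15 was then at -2.14 ± 0.75 (adjusted p = 0.0742), CCSER1 at -1.68 ± 0.60, MFAP5 at -1.59 ± 0.56, PEX5L at -1.57 ± 0.78 and GABRR1 at -1.42 ± 0.79, with larger standard errors than without the covariate. The groups overlapped in each of these falls. BMP15 ranged from 0.408 to 8.93 CPM in Cas9 and from 0.381 to 93.6 CPM in tdTomato libraries.

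**Figure D2:**
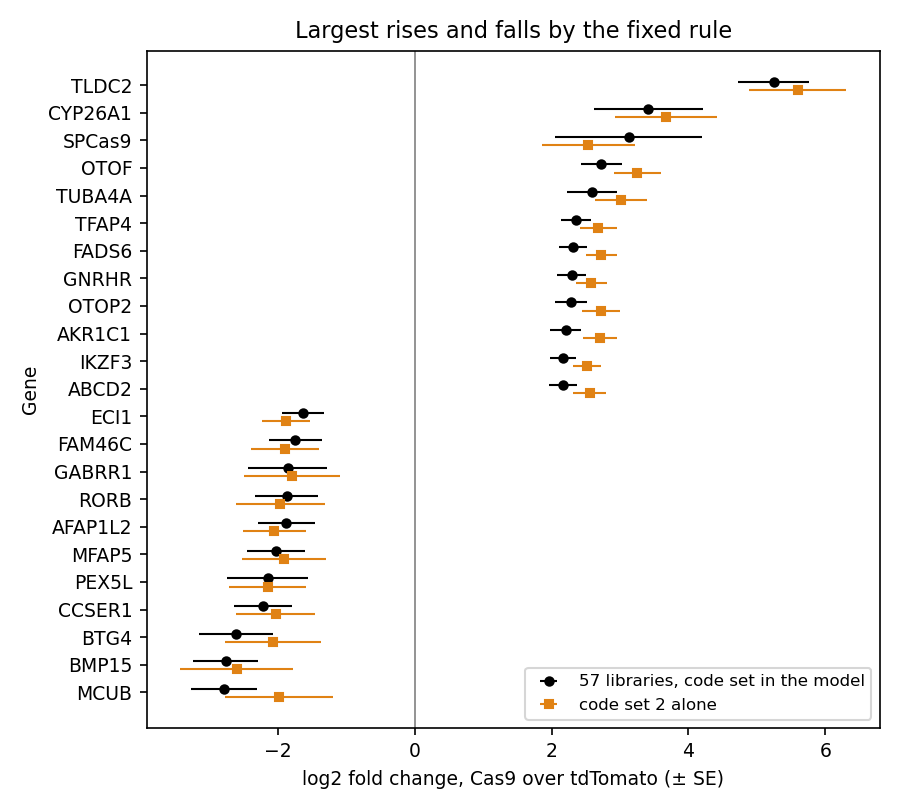
Log2 fold changes of Cas9 over tdTomato blastocysts with their standard errors for 12 rises and 11 falls taken by the fixed rule; circles are the model of 57 libraries with the code set as a term and squares are code set 2 alone (9 Cas9 and 18 tdTomato libraries). The rule took only genes with the same sign in code set 2; with every library scaled by its total alone, no sign of these 23 genes turned.

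In all, 3632 of 12086 tested genes passed an adjusted p under 0.05 in edgeR's quasi-likelihood test with the code set as a term, 1858 of them higher and 1774 lower in Cas9 blastocysts. The median log2 change was 1.36 for risen genes (10th to 90th percentile 0.54 to 1.92) and -0.55 for fallen genes (-1.09 to -0.35), so that 1314 genes were at least 2-fold higher and 220 at least 2-fold lower. That balance turned with libraries scaled by their totals alone, to 792 at least 2-fold higher and 1088 at least 2-fold lower. In code set 2 alone, 1732 genes were higher and 1662 lower of 11882 tested. The calls shared with all libraries were 1663 higher and 1321 lower with 0 in opposite directions, but code set 2 is part of both fits. The plain comparison without the code set term called 5398 genes, 2272 higher and 3126 lower. The first principal component of log2 CPM, with 23.7% of the variance, separated the groups, with Cas9 libraries between -5.11 and 71.6 and tdTomato libraries between -81.7 and -21.4. With libraries scaled by their totals alone, the split was 1362 higher and 6445 lower, where the median of all genes lay at -0.52 on the log2 scale and not at -0.12. With the KATNAL1 and MLST8 share as a covariate, 855 genes passed, 766 higher and 89 lower, and with the number of detected genes as a covariate 2367 passed. Of the called genes named in the text, those still past the threshold with that share as a covariate were TLDC2, OTOF, TUBA4A, TFAP4, FADS6, GNRHR, OTOP2, AKR1C1, IKZF3, ABCD2, RNF168, PRKDC, SMARCA4, BCL2, WIPI2, SNRPN, HSPE1 and RPL23 among rises and MCUB, BTG4, KPNA7 and UHRF2 among falls, while the others lost their call. Some of the lost calls had changes of about the same size or larger, such as DUXA at -1.78, ACACA at 0.85, CDKN1C at 0.93, SERPINE2 at 0.47, SLC2A3 at -1.10 and KDM1A at -0.38. Most of the rises that passed were smaller there, such as OTOF at 1.07, OTOP2 at 1.03, PRKDC at 0.63, WIPI2 at 0.48 and SMARCA4 at 0.45, while MCUB was at -2.95 and BTG4 at -2.54. At least 4 of up to 14 alternatives ended the calls of SPCas9 (6), PDGFRA (7), ACACA (8), and RRM2, SERPINE2, NFE2L2, CDKN1C and HSPD1 (4 each).

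**Figure D3:**
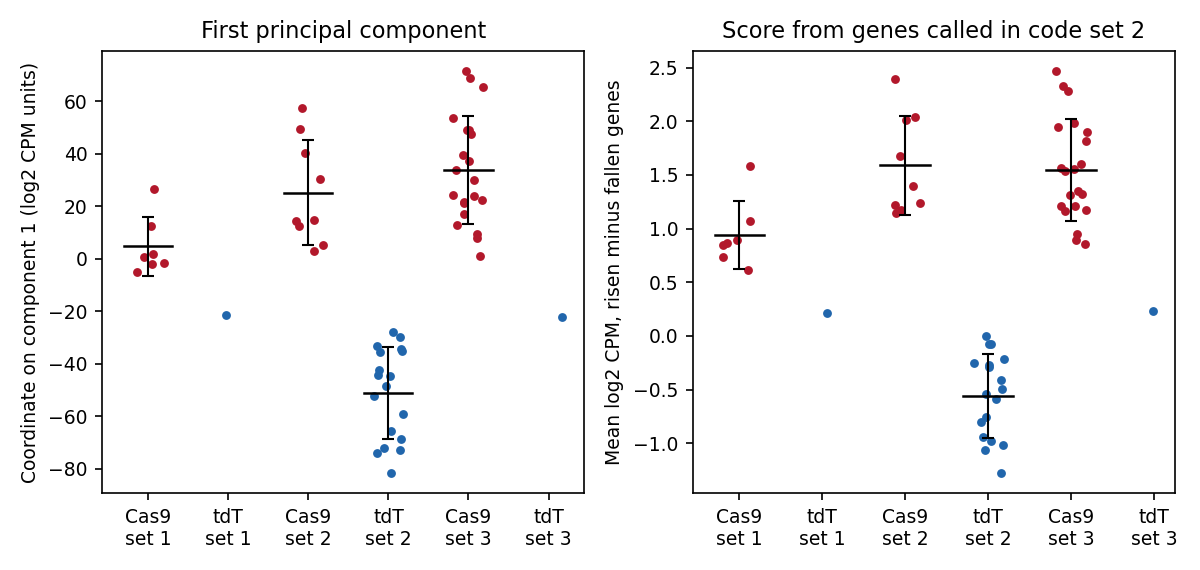
Left, coordinate of each library on the first principal component of log2 CPM; right, mean log2 CPM of the 1732 risen minus that of the 1662 fallen genes called in code set 2; points are libraries by group and code set (tdT, tdTomato), black lines and bars are mean ± SD. The lone tdTomato libraries of code sets 1 and 3, at 0.21 and 0.23 on the right-hand scale, lie under all Cas9 libraries of their sets, which start at 0.61 and 0.86.

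Oocyte and maternal-effect transcripts, which the egg stores and the embryo normally clears, were mostly lower in Cas9 blastocysts, although the call of the list depended on the test. Of 15 tested members, 10 fell, 0 rose and 5 did not pass (0 higher and 12 lower when adjusted over the list alone), with a median log2 change of -1.64. The growth factor GDF9 fell by 2.58 ± 0.44 on the log2 scale (adjusted p = 2.06e-06), and BMP15 and BTG4 are given above. The oocyte importin KPNA7 had a log2 fold change of -1.86 ± 0.36 (adjusted p = 2.65e-05). In camera with a preset correlation the list passed (adjusted p = 0.0152), but it did not with an estimated correlation (adjusted p = 0.863). In code set 2 the median was -1.44 and camera's adjusted p = 0.202, with 7 members lower and 0 higher, and KPNA7 did not pass there (adjusted p = 0.0694). The list's call was also lost without the lone tdTomato libraries of code sets 1 and 3 (median -1.37, adjusted p = 0.159), after thinning (median -1.77, adjusted p = 0.100) and with libraries scaled by their totals alone (median -2.08, adjusted p = 0.216). In code set 2, 15 of 18 tdTomato libraries had a higher list mean than the median Cas9 library.

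Cytosolic ribosomal protein genes were slightly higher in Cas9 blastocysts, with a median log2 change of 0.24 that turned to -0.18 when libraries were scaled by their totals alone, where the median of all genes lay at -0.52. Of 75 tested members, 36 rose, 0 fell and 39 did not pass (40 higher and 0 lower when adjusted over the list alone). RPL38 rose by 0.90 ± 0.13, RPS2 by 0.87 ± 0.12 and RPL23 by 0.86 ± 0.11 on the log2 scale (adjusted p = 7.98e-08, 2.86e-08 and 1.54e-09). The list passed in camera with a preset correlation (adjusted p = 2.85e-05) and not with an estimated correlation (adjusted p = 0.863). Ribosomal protein genes have many processed pseudogenes, and reads can be split among copies. The call was lost with the KATNAL1 and MLST8 share as a covariate (median 0.084, adjusted p = 0.124) and with the replicate number as a block (median 0.096, adjusted p = 0.130). Members of the same list also differed between code sets within Cas9 blastocysts, where the list passed only with the preset correlation, as given further on.

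**Figure D4:**
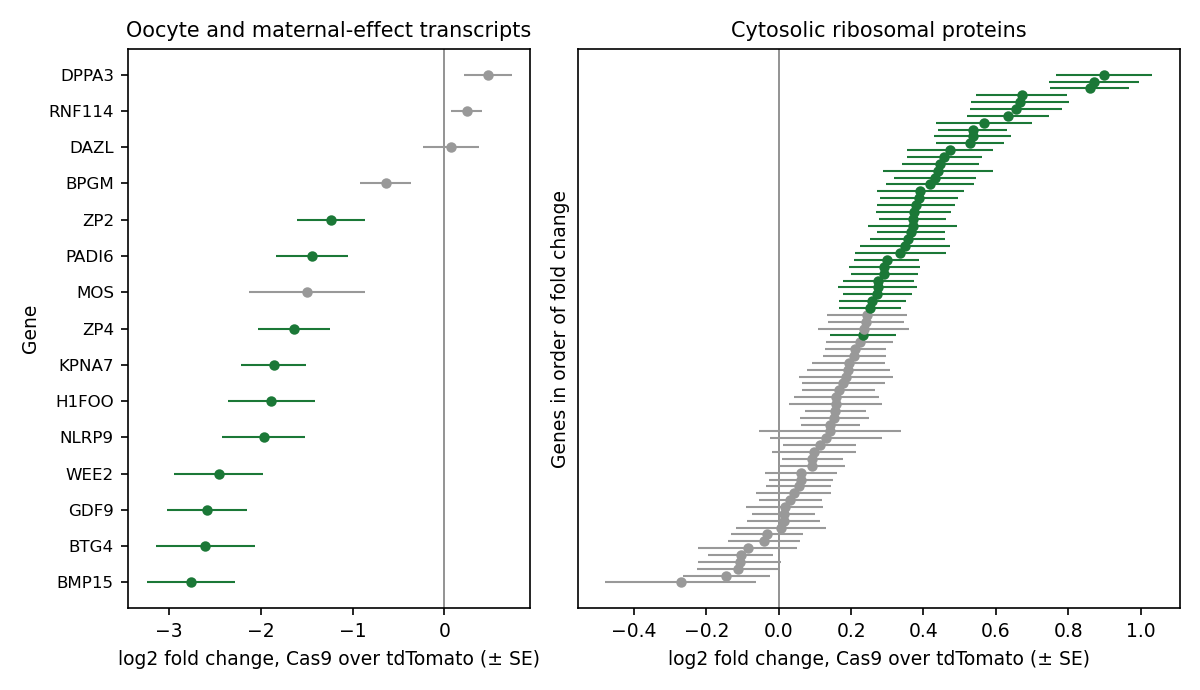
Log2 fold change of Cas9 over tdTomato blastocysts with its standard error for the tested members of the oocyte list (15 genes) and of the ribosomal protein list (75 genes); green points passed an adjusted p under 0.05 over all genes and grey points did not. Oocyte transcripts have a median of -1.64 and ribosomal protein genes of 0.24, the latter at -0.18 with libraries scaled by their totals alone.

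Transcripts of double-strand break signalling and repair went both ways. Of 35 tested genes, 7 rose, 7 fell and 21 did not pass (7 higher and 9 lower when adjusted over the list alone; list adjusted p = 0.824). The ubiquitin ligases RNF168 and RNF8, which mark chromatin at breaks, rose by 0.95 ± 0.10 and 0.92 ± 0.11 on the log2 scale, and PRKDC, the kinase of end joining, by 1.45 ± 0.15 (adjusted p = 6.05e-12, 5.35e-10 and 8.14e-12). With the KATNAL1 and MLST8 share as a covariate the call of RNF8 was lost (log2 0.36, adjusted p = 0.082). The cell cycle inhibitor CDKN1A was at -0.28 ± 0.31 (adjusted p = 0.523) and the ubiquitin ligase MDM2 at 0.04 ± 0.14 (adjusted p = 0.877). BAX, a promoter of cell death, had too few reads to test, with at most 11 reads in any library.

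Of 24 tested apoptosis genes, 3 rose, 5 fell and 16 did not pass, and the counts adjusted over the list alone were also 3 and 5 (list adjusted p = 0.844). The genes that rose act in opposite ways on cell death. BCL2, which blocks it, rose by 2.02 ± 0.26, APAF1, the scaffold of the apoptosome, by 1.05 ± 0.14, and CFLAR, an inhibitor of caspase-8 activation, by 0.76 ± 0.11 on the log2 scale. BCL2 was of low abundance, at 0.785 CPM in tdTomato and 3.44 CPM in Cas9 blastocysts. With the KATNAL1 and MLST8 share as a covariate APAF1 was at 0.50 and CFLAR at 0.23, and both calls were lost (adjusted p = 0.0729 and 0.364). The median of the list was -0.21 and its mean 0.036. Of 47 tested cell cycle and replication genes only RRM2 passed, at 0.65 ± 0.22 (adjusted p = 0.0184), and 0 passed when adjusted over the list alone (list adjusted p = 0.919). The median of that list was -0.07 and its mean 0.021. PCNA was at 0.13 ± 0.16, CCNB1 at -0.01 ± 0.17 and CDC45 at -0.34 ± 0.15, none of which passed (adjusted p = 0.591, 0.985 and 0.0894). CDC45 passed without the code set term (-0.38, adjusted p = 0.00777). With libraries scaled by their totals alone CDC45 (-0.73, adjusted p = 0.000474) and CCNB1 (-0.41, adjusted p = 0.042) passed.

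Few lineage markers of the blastocyst passed over all libraries. Of 17 tested inner cell mass and pluripotency genes, 0 passed over all genes or when adjusted over the list alone (list adjusted p = 0.919), with a median of -0.0028 and a mean of 0.13. POU5F1 was at -0.16 ± 0.23, NANOG at 0.91 ± 0.51, KLF5 at -0.47 ± 0.19 and TDH at 1.31 ± 0.60 on the log2 scale, with TDH past the threshold in code set 2 (adjusted p = 0.0486), NANOG in limma-voom (adjusted p = 0.0256) and KLF5 in 4 alternatives. SOX2 had at most 5 reads in any library and was not tested. NANOG had a mean of 18.1 reads per library, so only large changes were detectable at this depth. Of 31 tested trophectoderm genes, 2 rose, 4 fell and 25 did not pass (2 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.313). The transcription factor TFAP2A fell by 0.60 ± 0.16 and the tight junction protein CGN by 0.42 ± 0.13, while DLX5 rose by 1.62 ± 0.45 (adjusted p = 0.00248, 0.00906 and 0.00355). DLX5 was of low abundance, at 0.672 CPM in tdTomato and 2.28 CPM in Cas9 blastocysts. CDX2 was at -0.58 ± 0.26 and GATA3 at 0.11 ± 0.22 (adjusted p = 0.0752 and 0.762), with CDX2 past the threshold in 3 alternatives. Of 13 tested hypoblast genes, 1 rose, 1 fell and 11 did not pass (0 higher and 1 lower when adjusted over the list alone; list adjusted p = 0.856). The receptor PDGFRA rose by 1.13 ± 0.42, a call that 7 alternatives ended, and the laminin LAMC1 fell by 0.51 ± 0.17. GATA6 was at -0.24 ± 0.11 (adjusted p = 0.0926) and at -0.36 ± 0.11 in code set 2, where it passed (adjusted p = 0.0133). SOX17 had too few reads to test.

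Markers of cells that surround the oocyte did not pass as a list in camera. In fry, which does not compare members with other genes, they passed (adjusted p = 7.06e-06). Of 7 tested cumulus and granulosa markers, 2 rose and 5 did not pass (4 higher and 0 lower when adjusted over the list alone; list adjusted p = 0.263). INHBA, an activin subunit, rose by 1.38 ± 0.17 and the protease inhibitor SERPINE2 by 0.53 ± 0.15 (adjusted p = 2.87e-10 and 0.00521). FST, which binds activin, was at 0.94 ± 0.40 (adjusted p = 0.0648). FST passed without the code set term (adjusted p = 0.0104), in the DESeq2 Wald test (adjusted p = 0.0367) and after thinning (adjusted p = 0.0422). With the KATNAL1 and MLST8 share as a covariate INHBA was at 0.34 and lost its call (adjusted p = 0.183). Among blood and other somatic markers only PECAM1 (0.99 ± 0.56), LYZ (1.41 ± 0.61) and HBB (0.52 ± 0.57) were tested, and none passed in the main fit. PECAM1 passed without the code set term (1.10, adjusted p = 0.0261), with the replicate block (1.69, adjusted p = 0.0164) and in limma-voom (1.69, adjusted p = 0.0224). LYZ passed without the code set term (1.51, adjusted p = 0.0219), and HBB passed in no alternative.

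No stress or metabolic list passed as a list in camera, and single members changed. In fry the antioxidant list passed (adjusted p = 0.0222). Of all 12086 tested genes, 1858 rose and 1774 fell, so changed members alone do not mark a list. Of 24 tested antioxidant genes, 5 fell and 0 rose (0 higher and 4 lower when adjusted over the list alone; list adjusted p = 0.291). The ferritin heavy chain FTH1 fell by 0.69 ± 0.19, from 11147 CPM in tdTomato to 6505 CPM in Cas9 blastocysts, glutathione reductase GSR fell by 0.66 ± 0.17 and the regulator NFE2L2 by 0.30 ± 0.10 on the log2 scale. Of 36 tested genes of the unfolded protein and heat shock responses, 2 rose, 3 fell and 31 did not pass (1 higher and 0 lower when adjusted over the list alone; list adjusted p = 0.291). The mitochondrial chaperonins HSPE1 and HSPD1 rose by 1.00 ± 0.17 and 0.34 ± 0.11, the latter turning to -0.076 with libraries scaled by their totals alone, and the endoplasmic reticulum factor CRELD2 fell by 1.22 ± 0.43. Of 42 tested nuclear genes of oxidative phosphorylation, 2 rose and 6 fell (the same counts when adjusted over the list alone; list adjusted p = 0.291), among them the complex I subunit NDUFV1 at -1.05 ± 0.29 and the complex II subunit SDHB at -0.55 ± 0.15.

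Of 19 tested glycolysis genes, the glucose transporter SLC2A3 fell by 1.28 ± 0.36 and the isomerase GPI by 0.38 ± 0.11 on the log2 scale, also when adjusted over the list alone. In code set 2 GPI did not pass (adjusted p = 0.0947). With the replicate block SLC2A3 (-0.61, adjusted p = 0.208) and GPI (-0.25, adjusted p = 0.118) lost their calls. Without the code set term SLC2A3 was at -0.67 (adjusted p = 0.0234). Its Cas9 mean was 9.96 CPM in code set 2 and 18.1 CPM over all Cas9 libraries, against 28.7 CPM in tdTomato blastocysts. Over all libraries GAPDH was at -0.45 ± 0.21 (adjusted p = 0.106), and it passed with libraries scaled by their totals alone (-0.82) and with the KATNAL1 and MLST8 share as a covariate (-1.02, adjusted p = 0.0113). The list did not pass in camera (adjusted p = 0.341) and passed in fry (adjusted p = 0.0395). Of 34 tested proteasome genes, 1 rose and 5 fell (1 higher and 3 lower when adjusted over the list alone; list adjusted p = 0.343). PSMD6 rose by 0.98 ± 0.15, which turned to -0.027 with the KATNAL1 and MLST8 share as a covariate, and PSMB4 and PSMB5 fell by 0.36 ± 0.10 and 0.34 ± 0.10. Of 25 tested autophagy and lysosome genes, 3 rose and 6 fell (3 higher and 7 lower when adjusted over the list alone; list adjusted p = 0.576). WIPI2, which acts in autophagosome formation, rose by 1.36 ± 0.15 and the protease CTSL by 1.30 ± 0.28. Of 21 tested genes of sterol and fatty acid synthesis, HMGCS1 rose by 0.54 ± 0.19 and ACACA by 0.53 ± 0.21, neither when adjusted over the list alone, and in code set 2 ACACA did not pass (adjusted p = 0.0769), while SC5D was at -0.51 ± 0.24 (list adjusted p = 0.856).

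Genes of nucleic acid sensing changed about as often as tested genes at large, of which 1858 of 12086 rose and 1774 fell. Of 18 tested interferon and sensing genes, 4 rose, 2 fell and 12 did not pass, with the same counts when adjusted over the list alone (list adjusted p = 0.419). The RNA sensor DDX58, also named RIG-I, rose by 1.16 ± 0.17 and its adaptor MAVS by 1.07 ± 0.14 on the log2 scale (adjusted p = 9.49e-08 and 1.66e-09), and the downstream kinase TBK1 fell by 0.44 ± 0.14. The DDX58, MAVS and TBK1 calls were lost with the KATNAL1 and MLST8 share as a covariate.

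Among 36 tested DNA methylation and chromatin genes, 1 rose and 11 fell, with the same counts when adjusted over the list alone (median -0.21; list adjusted p = 0.291). The remodelling ATPase SMARCA4 rose by 1.60 ± 0.17 on the log2 scale (1467 ± 500 CPM in Cas9 (SD, n = 37) and 484 ± 187 CPM in tdTomato blastocysts (SD, n = 20); adjusted p = 3.76e-12). UHRF2 fell by 1.37 ± 0.23 and the histone demethylase KDM1A by 0.42 ± 0.10. Of 16 tested imprinted genes, 3 rose and 2 fell, also when adjusted over the list alone (list adjusted p = 0.612). SNRPN, normally expressed from the paternal allele, which parthenotes lack, rose by 1.79 ± 0.19 from 6.62 to 23.2 CPM. The growth inhibitor CDKN1C rose by 0.99 ± 0.30 at low abundance, from 1.03 to 1.97 CPM, and PPP1R9A fell by 0.80 ± 0.20. Of 17 tested genes of embryonic genome activation, 3 rose and 2 fell (4 higher and 2 lower when adjusted over the list alone; list adjusted p = 0.649). The homeobox gene OTX2 rose by 1.57 ± 0.31, and EIF1AX rose by 0.35 ± 0.09, which turned to -0.067 with libraries scaled by their totals alone. The early homeobox gene DUXA fell by 1.69 ± 0.51, at a low 3.90 CPM in tdTomato and 0.865 CPM in Cas9 blastocysts. Its call was lost in limma-voom (-1.21, adjusted p = 0.0993).

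The lone tdTomato libraries of code sets 1 and 3 gave a comparison outside code set 2. A score was formed from the genes called in code set 2, as the mean log2 CPM of the 1732 risen minus that of the 1662 fallen genes. In code set 1 the tdTomato library scored 0.21 and the 7 Cas9 libraries 0.94 ± 0.32 (SD). In code set 3 the tdTomato library scored 0.23 and the 21 Cas9 libraries 1.55 ± 0.47 (SD). The tdTomato library was the lowest of its set in both, the most extreme of 176 arrangements (exact permutation test, two-sided p = 0.00568). Both lone libraries scored above all tdTomato libraries of code set 2, the highest of which was at -0.00062. The rank thus does not show a difference of the same size as in code set 2, where the genes were chosen. Of the risen genes, 87.8% had the same sign in code set 1 and 91.4% in code set 3, and of the fallen genes 62.3% and 80.5%. A test of whether the Cas9 effect differed between code sets called 0 genes in edgeR, with 951 at an unadjusted p under 0.05, and it rests on these lone libraries.

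Within Cas9 blastocysts, more genes were called between code sets 1 and 3 than between either of them and code set 2. Code sets 1, 2 and 3 held 7, 9 and 21 Cas9 libraries, so the test of sets 2 and 1 had the fewest. RAC1, a small GTPase of the cytoskeleton, had a median of 20.1 RPM in the 7 Cas9 libraries of code set 1, 139 in code set 2 and 133 in code set 3 (adjusted p = 7.93e-14 for any difference between sets), and the tdTomato library of code set 1 had 19.8. LAGE3, a subunit of a tRNA-modifying complex, had medians of 2.05, 16.8 and 16.7 RPM, and 2.89 in the tdTomato library of code set 1 (adjusted p = 1.27e-13). COQ2, an enzyme of ubiquinone synthesis, had medians of 12.5, 51.0 and 46.0, and 10.6 in that tdTomato library. These genes, the first by p-value, were chosen after their values were seen. Ribosomal protein genes were higher in code set 3 than in code set 1, with 54 of 75 rising, 0 falling and a median log2 change of 0.58. Camera gave adjusted p = 6.35e-41 with a preset and adjusted p = 0.158 with an estimated correlation. Between code sets 2 and 1 their median was 0.42, with 7 of 75 rising and 0 falling. In edgeR's test, 979 of 12879 genes differed between any code sets, 1296 between sets 3 and 1, 72 between sets 2 and 1, and 65 between sets 3 and 2. Of 1265 genes that differed between sets 3 and 1 and were also tested between the treatments, 576 passed in both, 554 of them in the same direction; the fits share the Cas9 libraries.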

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

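Among the 7 Cas9 libraries of code set 1, the library with replicate number 4 had 225 SPCas9 RPM, where the next highest had 9.05; its gap was 0.968 of the range. This was the only value far from the rest among 10 sets of library values examined in groups of 7 and 9. Chance marks about 1 in 20 such sets if values are normally distributed. SPCas9 RPM is strongly skewed, so such a gap is to be met more often in it. No explanation was tested for it.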

How the results depend on the processing

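Scaling by library totals, thinning, the share of KATNAL1 and MLST8 reads, upper-quartile factors, length offsets, bias-adjusted dispersions and leaving out the most abundant genes were chosen after seeing the data; the other alternatives were planned. The count of 3632 genes between Cas9 and tdTomato blastocysts stayed within 1.5 times of that value in the other settings, including 5398 without the code set term, 3891 without a count filter (2494 higher and 1397 lower), 3658 with the DESeq2 Wald test and 3059 after thinning, and leaving out each tdTomato library in turn gave 3253 to 3936. It moved to 2367 with the number of detected genes as a covariate (1489 higher, 878 lower), to 7807 with library totals, where the median of all genes lay at -0.52, to 855 with the read share as a covariate, and to 1534 with a fold change of at least 2, which keeps fewer genes by construction; the cause of the others was not tested. Of the 3632 genes, 2194, 3136 and 838 passed in the same direction under the first 3 of these. Title numbers do not pair the libraries: 1 of 20 same-numbered pairs correlated above 0.1, the median correlation was -0.010, and 0 libraries correlated best with their own number. With those numbers as a replicate block, 3388 genes passed (1657 higher, 1731 lower). That fit held only title numbers up to 20 and had no code set term, so it does not show the effect of blocking alone.

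The 2 lists that passed became 1 in code set 2 alone, 1 without the 2 lone tdTomato libraries and 1 after thinning, each time the ribosomal list. With the replicate block 1 list passed, the oocyte list. Library totals left 0, camera's estimated correlation left 0, and fry called 9. Fry tests whether members move without comparing them with other genes. Its 9 lists included those of cumulus and granulosa, chromatin, antioxidant, glycolysis, interferon and imprinted genes. The cause of the other changes was not tested. The sterol and fatty acid list turned from below to above other genes with the read share as a covariate (median 0.48, adjusted p = 0.0393). EIF1AX and HSPD1 turned to -0.067 and -0.076 with library totals, and PSMD6 to -0.027 with the read share; these 3 values did not pass, and the cause of the 4 turns was not tested. Over 98 named genes and their alternatives, 1205 values kept direction and side of the threshold, or passed under neither, 117 lost their call, 54 of them with the read share, and 34 gained one. A sign changed in 22 values that passed under neither setting. Leaving out libraries of low depth removed 0 libraries, and the planned change of count source gave no value of its own, because the series table holds TPM. Depth limits the rarest transcripts: BAX, SOX2 and SOX17 were not testable.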

Other observations

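A few embryos carried single transcripts at levels far above the median of all libraries. VEGFA, the vascular growth factor, stood at 1474 and 1226 RPM in the Cas9 libraries with replicate numbers 6 and 7, both of code set 1, against a median of 2.66 over all libraries and 24.8 in the next highest. SDC4, a cell surface proteoglycan, stood at 834 in Cas9 replicate 24 against a median of 2.14 and 9.40 in the next. SPCas9 reached 642, 225 and 58.1 in Cas9 replicates 32, 4 and 30. TNC, an extracellular matrix glycoprotein, was above 25 times its median in 6 libraries of both groups, with 358 in tdTomato replicate 10 and 342 in Cas9 replicate 5. Of all rows, these and LOC100621706, highest at 497 in tdTomato replicate 15, were those with a maximum of at least 200 RPM and 100 times the median (or 100 times 1 where the median was lower). They were found by a search made after seeing the data.

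In a comparison made after seeing the data, genes annotated as lncRNA made up 20.8% of the genes that rose in Cas9 blastocysts (387 of 1858), 4.57% of those that fell (81 of 1774) and 8.80% of those tested. The odds ratio for risen against other tested genes was 3.71 and for fallen genes 0.454 (Fisher's exact tests over genes, which are not independent, p = 7.37e-71 and 2.74e-13).

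The tests on the KATNAL1 and MLST8 share, on whether a few tdTomato libraries carry a difference, and on equal depth by thinning were chosen after seeing the data, and the others before. Each count of genes was compared over 100 splits of the libraries, the real one included. A rank of 1 in 100 is the most this can show, and within that limit it argues against chance for the gene counts. The real split was the only 1 of 100 with as many genes for all libraries within code sets (3632, highest other 262), for code set 2 (3394, highest other 2036), without the code set term (5398, highest other 58) and between code sets within Cas9 blastocysts (979, highest other 894). In the last of these the highest other split came close to the real count. For the lists chance is not excluded: 81 of 100 splits gave at least the 2 lists of the real split, and the highest other gave 10. A camera p as small as the real one came from 18 splits for the oocyte list and from 29 for ribosomal proteins. A median as large in size came from the real split alone, with -1.64 against at most 1.51 in size for the oocyte list and 0.24 against at most 0.23 for ribosomal proteins.

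The 3632 genes that differ between the groups may reflect depth, since Cas9 libraries were deeper. Thinning every library to the smallest total left 3059 genes past the threshold, 2909 of them among the 3632 and in the same direction, which argues against depth as the whole cause. The uneven spread of the groups over code sets as the whole cause is argued against by the 3394 genes that passed within code set 2 alone. The injection itself and the form and dose of what was injected were not tested and remain open.

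The risen genes had log2 changes of 0.54 to 1.92 between their 10th and 90th percentiles. Genomic DNA would add about the same reads per kilobase to every gene, but that rise differed 314-fold between the 10th and 90th percentiles of the risen genes. This argues against genomic DNA as the only source of all these rises. A part in the rises of genes with few reads was not tested. A candidate explanation is an axis of variation, marked by the KATNAL1 and MLST8 read share, that also runs between embryos of a group. Across genes, the slope on that share within a group correlated with the Cas9 fold change. The correlation was r = 0.57 in Cas9 and r = 0.539 in tdTomato libraries. Of 99 other splits, 5 gave a smaller-of-both value as high (highest 0.618), where only positive values were counted. Random splits have no fixed direction, and some were as strong with the opposite sign, such as a split with r = -0.584 and -0.736. The correlations therefore do not set the real split clearly apart from random ones, and genes are not independent. That axis alone is argued against by the 855 genes that passed with the share as a covariate, although the share may mark it imperfectly and itself differs between the groups. What the axis is, biological or of the library preparation, stays open.

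Of 15 oocyte transcripts tested, 10 were lower in Cas9 blastocysts, while the call of the list was lost with an estimated correlation (adjusted p = 0.863) and in code set 2 (adjusted p = 0.202), and chance is not excluded for the lists. A few tdTomato libraries might carry this, but 15 of the 18 tdTomato libraries of code set 2 lay above the median Cas9 library of that set, which argues against it. For the same axis as that of the risen genes, within Cas9 libraries, with code set means removed, the list and the risen genes correlated at r = -0.103 (n = 37, 95% interval -0.42 to 0.24, permutation p = 0.554; Spearman's rho = -0.11, p = 0.523; r = 0.0879 without the 2 farthest libraries), and within the 18 tdTomato libraries at r = -0.217 (permutation p = 0.385; rho = -0.255, p = 0.304; r = -0.316 without 2). By code set, r in Cas9 libraries was -0.422 (n = 7), -0.0156 (n = 9) and -0.0768 (n = 21), and the smallest adjusted p of the 5 relations was 0.924 for r and 0.847 for rho (exact or sampled permutation tests). With the share as a covariate the list passed in camera at the preset correlation (adjusted p = 0.0107), with a median of -1.11 in place of -1.64, and an estimated correlation was not tried with that covariate. In Cas9 libraries the interval leaves out a strong relation (r below -0.5), which argues against an axis of that strength in both groups. A weaker shared axis stays open, since r in tdTomato libraries (95% interval -0.62 to 0.28) lay below the bound of -0.2 set in advance against it. A slower clearance of maternal transcripts in tdTomato embryos, or a difference in stage, was not tested.

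The hypothesis that the size of the response follows the Cas9 RNA left in the blastocyst was tested on the 37 Cas9 libraries, with log10 SPCas9 RPM and a score formed as above but from those genes called in code set 2 that were also tested over all libraries, without SPCas9. With code set means removed r was -0.0428 (95% interval -0.371 to 0.295, permutation p = 0.807) and -0.0417 without the 2 farthest libraries. Spearman's rho was 0.0749 (permutation p = 0.67). The upper end lay just under the bound of 0.3 set in advance. A shared linear relation of that strength is thus argued against by a narrow margin only. A weaker relation stays open, and the pooled value averages over code sets whose r differed in sign. By code set, r was -0.292 (n = 7, exact permutation p = 0.393; rho = -0.429), 0.655 (n = 9, exact permutation p = 0.0609, adjusted p = 0.244; rho = 0.817, exact p = 0.0108, adjusted p = 0.0431 over 4 relations) and -0.163 (n = 21, permutation p = 0.488; rho = -0.100). Code set 2, where r fell to 0.457 without its 2 farthest libraries, is thus an exception in rank, on a score built from genes called in these same libraries; whether the sets differ was not tested.

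The hypothesis that treatment changes the spread between embryos was tested in code set 2. The median over 12086 genes of the ratio of standard deviations, tdTomato over Cas9, was 1.03, inside the central range of 0.927 to 1.14 of 100 splits of centred values (highest other 1.18). In 2678 genes with a mean of at least 50 CPM it was 0.874, also inside its range (0.847 to 1.21).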
